A study of Homo sapiens with 6 samples.

How the data were processed

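RNA from DU145 cells of the shControl and shMEK5 groups, 3 samples each, was purified on RNeasy columns, amplified and labelled with Cy3 by the authors, and hybridised to 1-colour Agilent gene expression arrays. The scanner files hold the signal as intensity per spot, which per the file headers came from Agilent Feature Extraction 12.0.2.2 (12.0.2 in the submitters' notes). The processed signal is, per the file headers, an intensity after background subtraction and spatial detrending within the array, without scaling between arrays. The multiplicative detrending column is, per the file headers, a ratio, and this detrending was not applied on shControl 3. The authors' value table holds log2 values for 7299 probes, of which 7288 match the array design. Its values followed the log2 processed signal of the same array (r above 0.999 across probes, which are not independent replicates), but the scaling between arrays and the rule by which its probes were selected were not stated. It held 84.1% of the probes called here and 26.2% of those not called, so the scanner files gave every result and the authors' values served as an alternative.

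The processed signal was taken as log2 and each array's 75th percentile was subtracted. The 1377 control spots and the spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged, giving 34127 probes from 43118 spots. A probe was kept where it was well above local background on all 3 arrays of at least 1 group, which left 21317 probes. Probes were named by their RefSeq accession (26377), symbol (2223) or former symbol (342), and 5185 kept the name in the files. The brightest kept probe stood for each gene, which gave 16482 genes, 3920 of them with more than 1 kept probe. XIST and Y-linked genes were tested but left out of the written gene table. The current RefSeq annotation served for names and gene order, while the positions given are those of the probes in hg19 as in the files, which name no exon.

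The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with version 1.17.8 of data.table, without covariates. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called changed. Log2 fold changes are shMEK5 minus shControl. For a gene above background on no array of 1 group, the fold is a lower bound. Each of that group's values below the array's dimmest signal still well above background was raised to that signal before the fold was taken. The groups, the normalization, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

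The 32 gene lists were the MEK5-ERK5 module, ERK1/2 output and feedback, immediate early genes, non-homologous end joining, homologous recombination and Fanconi genes, G1/S and DNA replication, G2/M and mitosis, epithelial identity, mesenchymal identity, integrins and laminins, extracellular proteases and inhibitors, TGF-beta and SMAD targets, YAP/TAZ-TEAD targets, interferon response, antigen presentation, NF-kB targets and cytokines, p53 targets, apoptosis regulators, hypoxia and glycolysis, the unfolded protein and integrated stress response, NRF2 antioxidant targets, cholesterol and SREBP2 targets, fatty acid synthesis and SREBP1 targets, cytosolic ribosomal proteins, oxidative phosphorylation, replication-dependent histones, prostate stem and basal markers, androgen receptor luminal markers, neuroendocrine markers, fibroblast and stromal markers, leukocyte markers and endothelial markers. The 29 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Estimated correlations and limma's fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. With an estimated correlation camera also takes its p-values from fewer degrees of freedom, so a call can be lost without correlated members. Genes were named by rule: MAP2K5 and the module; the 12 largest rises and the 12 largest falls among protein-coding genes past the threshold whose groups did not overlap; and up to 4 members per list, those past the threshold with the smallest p, or those with the largest changes where none passed. Some genes that fit these rules are not reported here.

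Alternatives fixed in advance were quantile normalization, scaling by the median of detected probes, normexp background correction (offset 50) with the 75th percentile or with quantile normalization, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, outlier spots kept, an intensity trend, array weights, slide as a block, only the arrays of slide 2, replicate number as a block, limma's treat against a 1.2-fold change, probes in place of genes, the authors' table, and leaving out each array in turn. Chosen after the data were seen were a local spatial correction of each array against the median array (windows of 12 spot lines and 5 spot columns on each side, with spots over 2 log2 units off left out), the dim corner of shControl 3 left out, and each of these with slide 2 alone, slide as a block or a shControl array left out. Also chosen then were the order of genes along chromosomes, where the strongest run of at least 10 neighbours per chromosome, on changes limited to 2 log2 units, was set against 100 shuffled gene orders, and 17 gene families.

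The steps were tested on simulated data. Values were drawn for 3 and 3 arrays from each gene's mean and each group's SD and known changes added, and limma found 20.9% of 67 genes changed 2-fold, 62.0% of 71 changed 4-fold and 83.9% of 62 changed 8-fold, while 16.7% of the calls were false, more than the threshold aims at. With no gene changed it made 0 calls, with 6.92% of genes at an unadjusted p under 0.05. A list shifted by 0.50 log2 units was called by camera and by fry, and camera called 0 of the lists left unshifted. The simulated genes were drawn independently of each other, while the estimated correlation in the data was 0.35 for G2/M and mitosis. It was 0.12 for NF-kB targets and 0.066 for mesenchymal identity. Below the preset 0.01 were epithelial identity (-0.008), interferon response (0.006), the unfolded protein and integrated stress response (0.0002) and NRF2 targets (-0.023). The simulation therefore cannot show how often camera's preset correlation gives false calls for lists with correlated members.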

Results

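Transcript levels were measured in DU145, a human prostate cancer cell line that grows without androgen, after stable expression of a short hairpin RNA. The shControl group (3 samples) carried a scrambled hairpin and the shMEK5 group (3 samples) carried a hairpin against MEK5, the kinase encoded by MAP2K5, which activates the MAP kinase ERK5 (MAPK7). Cy3-labelled cRNA from each sample was read on 1 array per sample. Well above local background were 19288, 20164 and 22622 probes on the shControl arrays 1 to 3, and 22041, 21997 and 22046 on the shMEK5 arrays. The 75th percentile of the processed signal was 551, 615 and 958 on the shControl arrays and 1038, 831 and 927 on the shMEK5 arrays. The number of arrays limits the precision of every value, and the labels do not say that the replicates are separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

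As processed, the shControl arrays were noisier than the shMEK5 arrays. Replicate spots of a probe varied by 26.7%, 26.8% and 18.3% (coefficient of variation) on shControl 1, 2 and 3. On the shMEK5 arrays they varied by 6.89%, 4.72% and 5.05%. The shControl 3 value is without multiplicative detrending, and the others are after it. Before detrending the values were 35.7%, 34.2% and 18.3% on the shControl arrays and 18.2%, 15.5% and 17.6% on the shMEK5 arrays. On this measure shControl 3 was thus close to the shMEK5 arrays before that step. The median SD of a gene within its group was 0.39 log2 units in shControl and 0.19 in shMEK5. On shControl 3 a corner of 1139 spots was dim by a median of -6.86 log2 units and held the probes of 384 tested genes. Slide 1 held shControl 1 and 2, and slide 2 held shControl 3 and all shMEK5 arrays. Slide 1 thus gives no within-slide value, and a fold with slide as a block rests on shControl 3 alone.

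The comparison of shMEK5 with shControl asks which transcripts differ when MEK5 is depleted, the question that the series title names. MAP2K5, the target of the hairpin, averaged -2.08 ± 0.71 (SD, n = 3) in shControl and -3.25 ± 0.19 (SD, n = 3) in shMEK5, in log2 units from the array's 75th percentile. The difference of -1.18 ± 0.36 (SE) makes MAP2K5 2.26-fold lower, but its adjusted p over all genes was 0.155, so the target did not pass the test (unadjusted p 0.0141, and adjusted p 0.0307 over the module alone). The single MAP2K5 probe lies on chromosome 15 (hg19, from 67985864 to 67995691) and was above background on all 6 arrays. It read -1.64, -2.89 and -1.70 on the shControl arrays and -3.41, -3.04 and -3.30 on the shMEK5 arrays, so the groups did not overlap. Within slide 2 the MAP2K5 difference was -1.55, with an adjusted p of 0.143 with slide as a block. Without shControl 2 it was -1.58 (adjusted p 0.0423), and after a local spatial correction, chosen after the data were seen, -1.09 (adjusted p 0.0477). Over the alternatives other than slide 2 alone, which holds 1 shControl array, its adjusted p ran from 0.0273 to 0.489.

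Of the 13 tested members of the MEK5-ERK5 module, KLF4 and SQSTM1 rose and SGK1 fell. KLF4, a zinc finger transcription factor induced by ERK5 in endothelial cells, was 3.33-fold higher (log2 1.74 ± 0.19 SE, adjusted p 0.0113; probe on chromosome 9, hg19, from 110248049 to 110248108). SQSTM1, the autophagy adaptor p62, was 2.50-fold higher (log2 1.32 ± 0.23 SE, adjusted p 0.0402; chromosome 5, from 179263709 to 179263768). SGK1, a serum-induced kinase, was 5.40-fold lower (log2 -2.43 ± 0.30 SE, adjusted p 0.0161; chromosome 6, from 134490656 to 134490715). SGK1 lies in a run of lower genes on chromosome 6, and lay at -1.61 log2 units from the run's median. MEF2C had a difference of 0.97 (adjusted p 0.0723), but was above background on 1 of the shControl arrays, so that this value rests on shControl signal near the background. KLF2 had -0.89 (adjusted p 0.128), while MAPK7, which encodes ERK5, had 0.23 (adjusted p 0.536). Differences of the other module members were 0.23 for MAP3K2, 0.15 for MAP3K3, -0.34 for MEF2A, -0.15 for MEF2D, 0.15 for PRKCZ and -0.14 for PRKCI. Adjusted over the list alone, 3 members were higher and 3 lower. The module's median was 0.15 and its mean -0.03, and its shift did not pass camera's test (direction up, adjusted p 0.823; by fry adjusted p 0.0457). The module's median was -0.05 without shControl 3 and -0.13 with slide as a block, and ran from -0.08 to 0.18 with 1 array left out in turn.

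**Figure D1:**
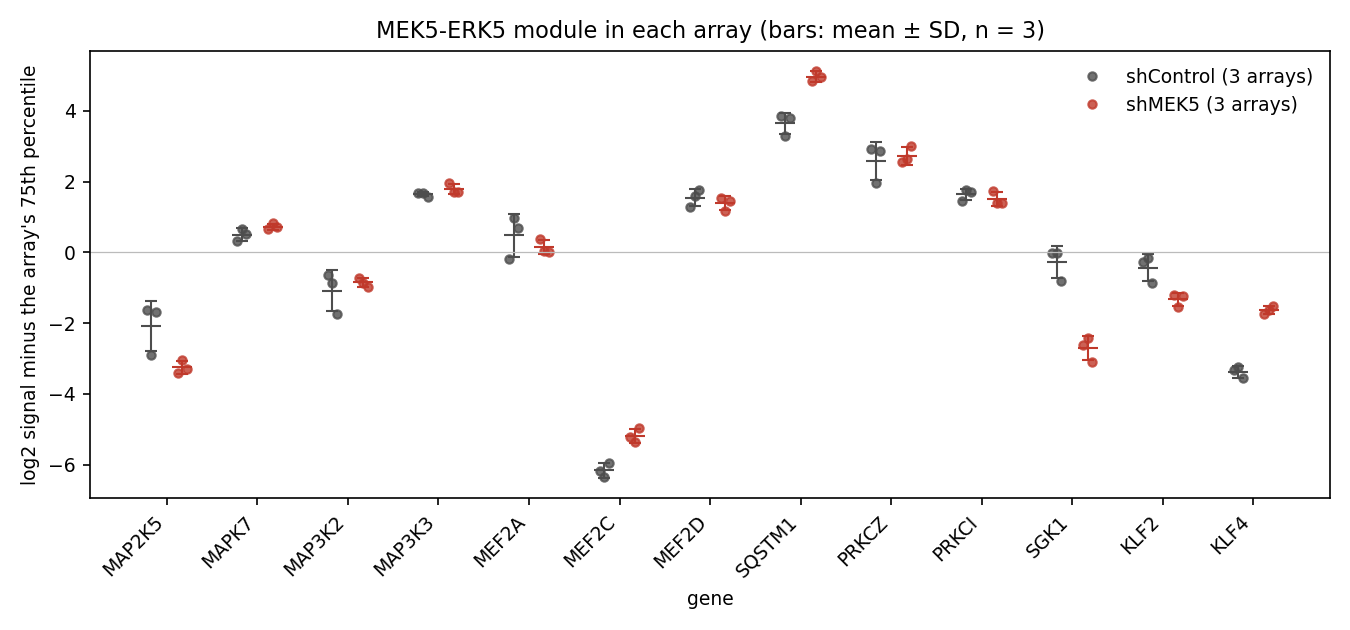
Log2 signal minus the array's 75th percentile (vertical axis) of the 13 module genes (horizontal axis) in shControl (grey) and shMEK5 (red); points are arrays and bars the mean ± SD, n = 3. MAP2K5 is lower in every shMEK5 array than in any shControl array (-3.25 against -2.08 on average), and KLF4, SQSTM1 and SGK1 are the members past adjusted p 0.05.

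Across the transcriptome, 358 of 16482 tested genes differed, 164 higher and 194 lower in shMEK5. Of these, 162 of the higher and 191 of the lower genes changed at least 2-fold, and 316 of the 358 were protein-coding. At an unadjusted p under 0.05 there were 3073 genes, and in 4521 genes (27.4%) the groups did not overlap, where chance gives 10%. With slide as a block 614 genes were higher and 228 lower, but 340 of the 614 lay in the dim corner of shControl 3. With that corner left out the blocked counts were 202 higher and 103 lower, and after the spatial correction 298 and 272. The slide 2 arrays alone gave 1038 higher (350 in the corner) and 888 lower, and 438 and 375 after the spatial correction, but with 1 shControl array the spread in these counts is that of the quieter shMEK5 arrays alone. Leaving out shControl 1, 2 or 3 gave 194, 138 and 1763 genes, and leaving out shMEK5 1, 2 or 3 gave 19, 10 and 35. The spatial correction over all arrays gave 686 higher and 589 lower.

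Among the largest rises that passed the test, SPINK1, a secreted trypsin inhibitor, was 15.0-fold higher (log2 3.91 ± 0.25 SE, adjusted p 0.00289; chromosome 5, hg19, from 147204211 to 147207585). DNER, a transmembrane Notch ligand, was 15.4-fold higher (log2 3.95 ± 0.29 SE, adjusted p 0.00395), and the tyrosine kinase SYK 11.6-fold (log2 3.54 ± 0.21 SE, adjusted p 0.00289). AP1M2, the epithelial subunit of the AP-1 clathrin adaptor, was 8.84-fold higher (adjusted p 0.0251). SPINK1, DNER, SYK and AP1M2 were each above background on 1 of the shControl arrays, so that these folds rest on shControl values near the background. ARSD, an arylsulfatase, was 13.3-fold higher by its brightest probe, but its 3 probes disagreed (-0.64, 3.73 and 1.83). The other rises were of genes above background on none of the shControl arrays, and are lower bounds. The metalloprotease ADAMTS9 was at least 7.50-fold higher, the kinesin KIF1A at least 12.2-fold and the Wnt pathway transcription factor LEF1 at least 4.88-fold. The adhesion molecule CEACAM6 was at least 3.33-fold higher, the collagen COL8A1 at least 3.64-fold, DCDC2 at least 3.62-fold and the kinase CAMK2B at least 4.47-fold. With normexp background correction and 75th percentile scaling no gene passed and the median of all genes was -0.28, and LEF1, CEACAM6, COL8A1, DCDC2, AP1M2 and CAMK2B lay below that median, while ADAMTS9, DNER and SYK were negative but above it.

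Among the largest falls, GJA1, which encodes the gap junction protein connexin 43, was above background on all shControl and on none of the shMEK5 arrays, at least 37.8-fold lower (adjusted p 0.00289; chromosome 6, hg19, from 121770327 to 121770386). FGB, the fibrinogen beta chain, was at least 24.5-fold lower (adjusted p 0.00269; chromosome 4, from 155492029 to 155492088). The bombesin receptor GRPR was at least 9.11-fold lower, the calcium channel subunit CACNG7 at least 10.3-fold and the mannosidase MAN1A1 at least 10.7-fold. SOBP was at least 6.62-fold lower and NAP1L2 at least 3.96-fold. STK31 was 19.0-fold lower (log2 -4.25 ± 0.41 SE, adjusted p 0.00809). It was above background on 2 of the shMEK5 arrays, so that this fold rests on shMEK5 values near the background. RNF43, a ubiquitin ligase that limits Wnt receptors, was 12.2-fold lower (log2 -3.61 ± 0.31 SE, adjusted p 0.00590). CCN2, a matricellular growth factor, was 11.2-fold lower (log2 -3.49 ± 0.34 SE, adjusted p 0.00816), and the cytokine IL24 10.9-fold (log2 -3.45 ± 0.29 SE, adjusted p 0.00590). GJA1, MAN1A1, SOBP and CCN2 lie in the run of lower genes on chromosome 6. CCN2 lay at -2.67 log2 units from the run's median. The fitted values of GJA1, MAN1A1 and SOBP lay at -6.21, -3.15 and -2.89 from it. These 3 distances rest on shMEK5 values not above background, and are neither measured sizes nor bounds.

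**Figure D2:**
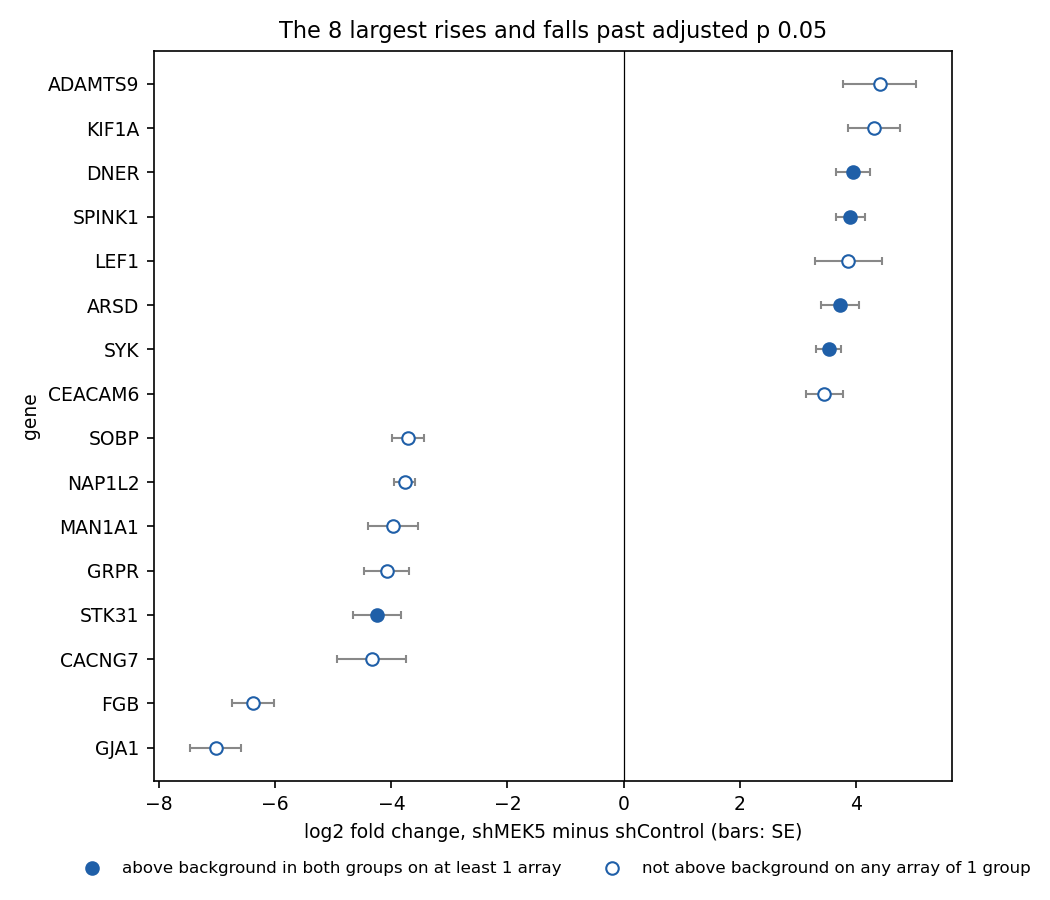
Log2 fold change, shMEK5 minus shControl (horizontal axis), of the 8 largest rises and the 8 largest falls among protein-coding genes past adjusted p 0.05 (vertical axis); bars are the SE, n = 3 per group. Open points, such as GJA1 and FGB, mark genes above background on no array of 1 group, whose fitted values are no bound; no gene passes with normexp background correction and 75th percentile scaling, which moves the median of all genes to -0.28.

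Camera called the epithelial list higher and the mesenchymal list lower, but neither with an estimated correlation, and members of each went both ways. Of 28 tested epithelial identity genes 5 passed the test, all of them higher, and adjusted over the list alone 11 were higher and 2 lower. The list's median was 0.28 and camera called it higher (adjusted p 0.00148; adjusted p = 0.181 with an estimated correlation). MAL2, an apical transport protein, was 5.93-fold higher (log2 2.57 ± 0.20 SE, adjusted p 0.00434), the tight junction gene CLDN7 4.47-fold, the transcription factor OVOL2 2.95-fold and the membrane serine protease ST14 2.61-fold. Of 20 mesenchymal identity genes 4 passed, all of them lower, and adjusted over the list alone 5 passed, again all lower. The mesenchymal median was -0.51 and the list was lower (adjusted p 0.00148; adjusted p = 0.327 with an estimated correlation). The matrix metalloprotease MMP14 was 3.10-fold lower (log2 -1.63 ± 0.23 SE, adjusted p 0.0242), the actin-binding TAGLN 2.85-fold, the lysyl oxidase LOXL2 2.49-fold and the repressor SNAI2 2.22-fold. Within slide 2, with slide as a block, the epithelial median was 0.33 (adjusted p 0.0186) and the mesenchymal -0.63 (adjusted p 0.000129). Without shControl 3 the mesenchymal list missed the threshold (median -0.43, adjusted p 0.0756).

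Among genes of adhesion and matrix, single members passed while no list shift passed camera's test under the main setting. Of 21 integrins and laminins 2 passed, both lower, and adjusted over the list alone 1 was higher and 2 lower (median -0.21, adjusted p 0.395; by fry adjusted p 0.0449). The integrin and laminin median was -0.01 without shControl 3 and 0.04 after the spatial correction, where 2 members were higher and 2 lower. ITGB2, the leukocyte integrin beta chain, was 6.89-fold lower (adjusted p 0.00292), although its dimmer probe gave a positive difference (adjusted p 0.536), and ITGA1 was 2.94-fold lower (adjusted p 0.0271). Of 16 extracellular proteases and inhibitors 1 rose and 2 fell, with the same counts adjusted over the list alone (median -0.21, adjusted p 0.269). The collagenase MMP1 was 9.88-fold lower (log2 -3.30 ± 0.35 SE, adjusted p 0.0105) and MMP14 fell too, while MMP24 was 2.39-fold higher (adjusted p 0.0360). Of 18 TGF-beta and SMAD targets INHBA, an activin subunit, passed as higher (adjusted p 0.0110), and was also the 1 member that passed adjusted over the list alone (median 0.13, adjusted p 0.221; by fry adjusted p 0.0449). INHBA was above background on 1 of the shControl arrays, and read -0.47 with normexp background correction and 75th percentile scaling, where the median of all genes was -0.28. Of 18 YAP/TAZ-TEAD targets 2 passed, both lower, CCN2 and the ectonucleotidase NT5E (4.02-fold, adjusted p 0.0470), and adjusted over the list alone 1 was higher and 5 lower. The YAP/TAZ-TEAD median was -0.41 (adjusted p 0.0962; by fry adjusted p 0.0266), or -0.23 without shControl 3 (adjusted p 0.322), and with both called members, which lie on the long arm of chromosome 6, left out the list's adjusted p was 0.443. After the spatial correction this list passed (median -0.30, adjusted p 0.0340), but not with an estimated correlation (adjusted p 0.291).

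Interferon response genes were called higher and NF-kB targets lower by camera, but neither with an estimated correlation, and members went both ways. Of 29 interferon response genes 1 rose and 1 fell, and adjusted over the list alone 6 were higher and 1 lower. The interferon median was 0.39 (adjusted p 0.00148; adjusted p = 0.181 with an estimated correlation), but -0.22 with normexp background correction and 75th percentile scaling, where the median of all genes was -0.28. IFIH1, the cytosolic RNA sensor MDA5, was 2.53-fold higher (adjusted p 0.0367) and IFITM3, an inhibitor of virus entry, 2.21-fold lower (adjusted p 0.0421). With slide as a block the interferon median was 0.22 (adjusted p 0.131), and 0.29 after the spatial correction (adjusted p 0.0269). Of 31 NF-kB targets and cytokines 2 rose and 2 fell, and adjusted over the list alone 2 were higher and 9 lower (median -0.41, adjusted p 0.0109; adjusted p = 0.591 with an estimated correlation and 0.100 by fry). The chemokine CCL2 was 4.45-fold higher (adjusted p 0.0304) and the siderophore-binding LCN2 5.06-fold (adjusted p 0.0458), while the acute phase gene SAA1 was 3.48-fold lower (adjusted p 0.0403) and the adhesion molecule ICAM1 2.33-fold (adjusted p 0.0388). With slide as a block the NF-kB median was -0.60 (adjusted p 0.0146), while it was -0.46 without shControl 3 (adjusted p 0.0739) and -0.19 without shControl 1 (adjusted p 0.0442). Of 17 antigen presentation genes the class II gene HLA-DRB1 fell 2.35-fold (adjusted p 0.0412), and adjusted over the list alone 1 was higher and 1 lower (median -0.04, adjusted p 0.590).

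Stress and metabolic genes held a pair of lists that camera called higher, but neither with an estimated correlation. Of 22 NRF2 antioxidant targets AKR1C1, a steroid-reducing aldo-keto reductase, rose 4.34-fold (log2 2.12 ± 0.25 SE, adjusted p 0.0148), and adjusted over the list alone 3 members passed, all higher. With normexp background correction and 75th percentile scaling AKR1C1 read -0.17, above the median of all genes (-0.28). Related aldo-keto reductases on this list may share signal by cross-hybridisation, which was not tested. The NRF2 median was 0.47 (adjusted p 0.00148; adjusted p = 0.181 with an estimated correlation), and 0.42 with slide as a block (adjusted p 0.00108). Of 24 genes of the unfolded protein and integrated stress response CHAC1, a glutathione-degrading enzyme, rose 2.67-fold (adjusted p 0.0478), and adjusted over the list alone 5 were higher and 1 lower. That median was 0.26 (adjusted p 0.0254; adjusted p = 0.281 with an estimated correlation), 0.33 with slide as a block (adjusted p 0.0791), 0.28 without shControl 2 (adjusted p 0.0573), 0.32 without shControl 3 (adjusted p 0.0739) and 0.41 without shMEK5 1 (adjusted p 0.0154). Of 30 hypoxia and glycolysis genes the hexokinase HK2 fell 2.94-fold (adjusted p 0.0165), and adjusted over the list alone 2 were higher and 5 lower. The hypoxia and glycolysis median was -0.27 (adjusted p 0.0962), and -0.57 with slide as a block (adjusted p 0.0471), but with an estimated correlation over all arrays the list's adjusted p was 0.592.

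Camera also did not call the lists of cholesterol and SREBP2 targets (23 genes, median 0.06, adjusted p 0.666), fatty acid synthesis and SREBP1 targets (14 genes, median -0.24, adjusted p 0.395), oxidative phosphorylation (30 genes, median 0.12, adjusted p 0.590) and cytosolic ribosomal proteins (34 genes, median 0.15, adjusted p 0.185; by fry adjusted p 0.0457). In none of these did a member pass limma's test, over all genes or adjusted over the list alone, and 2, 2, 3 and 2 members had an unadjusted p under 0.05. HMGCS1, of sterol synthesis, had a difference of 1.01 (adjusted p 0.207), INSIG1 0.71, STARD4 -0.67 and FDPS 0.36. ME1, on the long arm of chromosome 6, had -0.85 (adjusted p 0.172), GPAM 0.63, ACSS2 0.58 and ELOVL6 -0.53. NDUFV1 had 0.62 (adjusted p 0.181), SDHA 0.68, NDUFB3 -0.61 and ATP5F1B -0.60. RPL11 had 0.61 (adjusted p 0.240), RPL37 0.52 and RPL19 0.44.

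Mitotic genes were called lower as a group by camera, but not with an estimated correlation, and the shift did not hold within slide 2. Of 36 G2/M and mitosis genes 0 passed limma's test in either direction, over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05. The G2/M median was -0.33 (camera adjusted p 0.00148, or 0.592 with an estimated correlation, and 0.193 by fry). It was -0.16 with slide as a block (adjusted p 0.507) and -0.08 within slide 2 after the spatial correction. With normexp background correction and 75th percentile scaling camera's test was directed up but called no shift (adjusted p 0.943). CDC20, the activator of the anaphase-promoting complex, had a difference of -1.08 (adjusted p 0.0579), TTK -0.99 (on the long arm of chromosome 6) and TPX2 -0.90. ANLN had 2.75, a value that rests on the dim corner of shControl 3 (-0.74 after the spatial correction). The G1/S and DNA replication list (36 genes, median 0.14, adjusted p 0.116) held 0 genes past limma's test, over all genes or adjusted over the list alone, and 6 with an unadjusted p under 0.05. CDT1, a replication licensing factor, had 1.09 (adjusted p 0.0922), MCM10 0.98 and E2F8 0.91, while MCM6 had 2.12 because of the dim corner and 0.33 after the spatial correction. With slide as a block the G1/S median was 0.27 (adjusted p 0.0186), but 0.06 without shControl 3 (adjusted p 0.586), and with an estimated correlation over all arrays the list's adjusted p was 0.690. Replication-dependent histones (13 genes, median 0.18, adjusted p 0.611) held 0 members past limma's test, over all genes or adjusted over the list alone, and 0 with an unadjusted p under 0.05. H2BC12 had -0.49, H4C8 0.44, H2BC21 -0.43 and H2AC6 0.42.

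Neither DNA repair list passed the shift test. Of 30 genes of homologous recombination and the Fanconi pathway FANCE, a core complex member, fell 2.07-fold (adjusted p 0.0496), and was also the 1 member that passed adjusted over the list alone (median 0.24, adjusted p 0.269). Of 19 non-homologous end joining genes 0 passed limma's test, over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. That list had a median of -0.01 and a mean of 0.19 and was directed up (adjusted p 0.843), with TP53BP1 at 3.38 because of the dim corner and at 0.21 after the spatial correction. POLM had 0.76 (adjusted p 0.111), SHLD1 0.49 and LIG4 -0.37.

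Few genes of signalling output and survival passed the test, and no shift of these lists did. Of 21 genes of ERK1/2 output and feedback 0 passed limma's test, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median -0.11, adjusted p 0.443). The EPHA2 difference of 2.47 rests on a low shControl 3 value (-7.84, against 0.28 and 0.46 on the other shControl arrays), while SPRY1 had -0.60, DUSP5 -0.57 and PHLDA1 -0.49. Of 15 immediate early genes the nuclear receptor NR4A3 fell 2.73-fold (adjusted p 0.0439), and adjusted over the list alone 1 was higher and 3 lower. The immediate early median was 0.15, against a mean of -0.03 and a test directed down (adjusted p 0.986). Of 26 apoptosis regulators 3 passed, all of them higher, and adjusted over the list alone 3 were higher and 3 lower (median -0.17, adjusted p 0.590). The pro-apoptotic genes BMF and HRK rose 5.76-fold (adjusted p 0.0321) and 5.36-fold (adjusted p 0.0110), and the anti-apoptotic BCL2 passed as higher (adjusted p 0.0439). BCL2 was above background on 1 of the shControl arrays, and read -0.86 with normexp background correction and 75th percentile scaling, where the median of all genes was -0.28. Of 25 p53 targets SESN1, on the long arm of chromosome 6, fell 2.13-fold (adjusted p 0.0420), and adjusted over the list alone 4 members passed, all lower (median -0.01, adjusted p 0.666).

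Lineage and cell type markers gave few changes. Of 13 prostate stem and basal markers KLF4 rose and the basal keratin KRT15 fell 3.34-fold (adjusted p 0.0209), and adjusted over the list alone 1 was higher and 2 lower (median 0.04, adjusted p 0.890). Of the markers of androgen-responsive luminal cells 7 were tested and 0 passed limma's test, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (median 0.32, adjusted p 0.843). NDRG1 had 3.26 because of the dim corner and -0.05 after the spatial correction, PMEPA1 had 0.78 and KLK2 -0.68. Among 10 tested leukocyte markers the receptor CSF1R rose, at least 2.24-fold (adjusted p 0.0277), and was also the 1 member that passed adjusted over the list alone, but read -0.84 with normexp background correction and 75th percentile scaling, where the median of all genes was -0.28. The leukocyte median was -0.20, its mean -0.01 and its test directed down (adjusted p 0.890). With 4 tested genes or fewer, 3 lists got counts only. Of 4 fibroblast and stromal markers TAGLN fell, adjusted over the list alone too, and TAGLN, COL1A1 and ACTA2 are mesenchymal list members as well. Of 4 endothelial markers 0 passed limma's test, over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05 (ESAM 0.63, CDH5 0.59, EGFL7 0.41 and ROBO4 -0.23). Of 3 neuroendocrine markers 0 passed, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (FOXA2 1.21, ENO2 0.18 and CHGA, above background on none of the shControl arrays, at least 1.37-fold higher without passing).

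**Figure D3:**
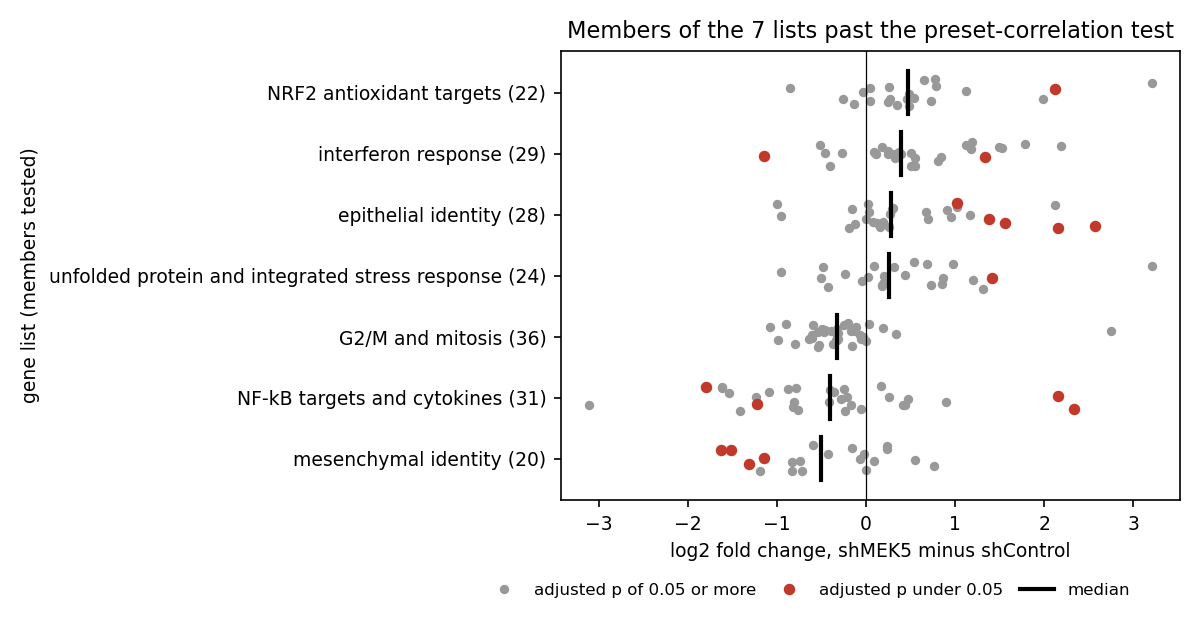
Log2 fold change, shMEK5 minus shControl (horizontal axis), of the tested members of the 7 gene lists that camera called with the preset correlation (vertical axis); red points passed adjusted p 0.05 and black bars are medians. Medians run from -0.51 (mesenchymal identity) to 0.47 (NRF2 targets), and none of the 7 calls held with an estimated correlation. With normexp background correction and 75th percentile scaling the interferon median is -0.22. The G2/M test by camera is then directed up without a call (adjusted p 0.943).

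Lower transcripts clustered on chromosome 6, a comparison chosen after the data were seen. In genome order, 292 tested genes from ZNF451 to TBP, which begin on the short arm and take in the long arm (probes from 57033933 to 170881700, hg19), had a median log2 fold change of -0.82, and 89.7% of them were lower. With slide as a block the median was -0.91, and within slide 2 after the spatial correction -0.82. The run held 48 calls, all of them lower, which is 24.7% of the 194 lower calls, although it held 1.77% of the tested genes. Relative to each gene's mean over the 6 arrays, the run's median lay at 0.40, 0.46 and 0.51 on the shControl arrays and at -0.29, -0.43 and -0.45 on the shMEK5 arrays. Chromosome 21 from NRIP1 to PRMT2 had a median of -0.33 over 159 genes, and chromosome 5 from NPR3 to GFPT2 had 0.17 over 582 genes. The 10 genes from SNX11 to PRAC2 on chromosome 17, which include the HOXB cluster, had a median of -1.37. Of these genes 100% were lower, and 5 passed the test. These 4 runs were stronger than any run in 100 shuffled gene orders.

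**Figure D4:**
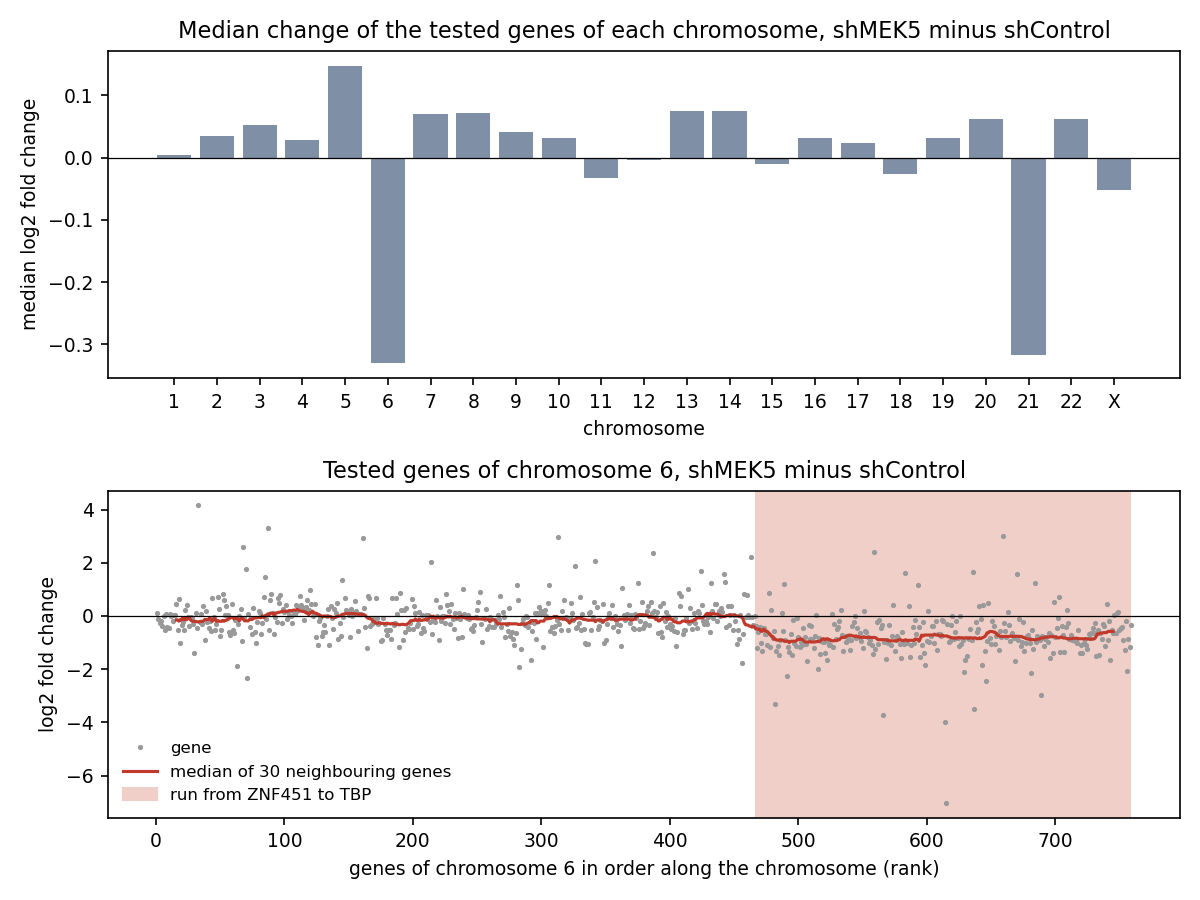
Upper panel: median log2 fold change, shMEK5 minus shControl (vertical axis), of the tested genes of each chromosome (horizontal axis). Lower panel: log2 fold change of the chromosome 6 genes in genome order (points), the median of 30 neighbouring genes (line) and the run from ZNF451 to TBP (shaded), whose median is -0.82.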

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

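The settings with the spatial correction or with the dim corner left out were chosen only after the data had been seen, and the other alternatives before. Quantile normalization, scaling by the median of detected probes, the mean of a gene's probes, outlier spots kept, an intensity trend, array weights, a filter on all 6 arrays and probes in place of genes kept both counts of changed genes (164 higher, 194 lower) within 1.5 times. Higher and lower counts moved further with no filter on dim probes (32 and 36, more genes tested), limma's treat against a 1.2-fold change (81 and 101), the replicate number as a block (35 and 33) and the authors' values (42 and 21, fewer genes tested). Deviations from the group mean had r of 0.0008, 0.083 and 0.144 across genes between same-numbered arrays. Between different-numbered arrays r ran from -0.128 to 0.106. These small values do not settle whether the numbers pair the samples, and the labels do not say. Normexp background correction gave 0 and 0 with the 75th percentile (1316 at an unadjusted p under 0.05 by limma) and 68 and 115 with quantile normalization. It left no common floor, since corrected 5th percentiles were 494, 195 and 58.7 on the shControl arrays and 59.7, 183 and 58.3 on the shMEK5 arrays. With the 75th percentile it moved the median of all genes to -0.28. Dim genes that had risen then read negative: ADAMTS9 -0.28, DNER -0.13, LEF1 -0.53, SYK -0.0202, CEACAM6 -0.68, COL8A1 -0.65, DCDC2 -0.55, AP1M2 -0.33, CAMK2B -0.62, INHBA -0.47, CCL2 -0.00822, BCL2 -0.86, AKR1C1 -0.17 and CSF1R -0.84. The G2/M median was then -0.0853, above that of all genes. With the filter on all 6 arrays ARSD read -0.64, because another of its probes then stood for it.

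Slide as a block moved the higher count to 614, and slide 2 alone, where 1 shControl array leaves the spread to the quieter shMEK5 arrays, gave 1038 higher and 888 lower. Blocked, the count with the dim corner left out was 103 lower, and that with the spatial correction 298 higher. Slide 2 alone with the spatial correction gave 438 and 375. The spatial correction over all arrays gave 686 and 589, and the dim corner left out 316 higher. Leaving out 1 array in turn gave from 3 (without shMEK5 2) to 1105 (without shControl 3) higher and from 7 to 658 lower genes, and with the spatial correction, without shControl 1, 2 or 3, 361 and 360, 300 and 315, and 1635 and 1234. The noisier shControl arrays and the fewer arrays both enter these counts, and the cause of the differences was not tested further.

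MAP2K5 was negative under every alternative. It read -1.55 with slide 2 alone and -1.51 with that and the spatial correction, where a pass rests on 1 shControl array and no shControl spread. It passed with the spatial correction (-1.09), with it and slide as a block (-1.51), and with it without shControl 2 (-1.36) or shControl 3 (-0.87). Leaving out 1 array in turn gave from -1.58 to -0.96, and past the threshold without shControl 2 alone. The cause was not tested, though shControl 2 is the shControl array nearest the shMEK5 values.

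Of the lists, 4 were higher and 3 lower. With an estimated correlation 0 and 0 were called, also after the spatial correction, with 4 lists at an unadjusted p under 0.05 by camera each time. Fry's test for 1 direction called 7 higher and 3 lower. It did not call G2/M and mitosis (adjusted p 0.193) or NF-kB targets (adjusted p 0.100), which camera did, and called the MEK5-ERK5 module (adjusted p 0.0457), integrins and laminins (0.0449), TGF-beta targets (0.0449), YAP/TAZ-TEAD targets (0.0266) and ribosomal proteins (0.0457), which camera did not. Its mixed test, which ignores direction, called 23 lists. Normexp with the 75th percentile called 9 higher and 1 lower, no filter 7 higher, and the authors' values 0 higher and 1 lower. Lists lower were 5 with the spatial correction and with it without shControl 1 or 2. Leaving out 1 array in turn gave from 1 (without shControl 3) to 5 (without shControl 1) lower and 3 to 5 higher. The cause was not tested in these cases. Over the single named genes, 1795 of the values under the alternatives fixed in advance kept direction and side of the threshold, 385 kept direction but not the call, 37 gained one and 15 reversed. Signal over background limits the genes above it on no array of 1 group, for which folds are bounds.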

Other observations

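The gene families, the runs along chromosomes and their test against random gene orders, and all settings with the spatial correction were chosen only after the results had been seen. Of 17 gene families tested as lists, camera called 3, and none of these passed with an estimated correlation. The aldo-keto reductases (8 genes) had a median of 1.16 (adjusted p 0.0103; adjusted p = 0.187 with an estimated correlation), which was -0.30 with normexp background correction and 75th percentile scaling. AKR1C1 passed the test for single genes (with the spatial correction it read 1.95), while AKR1C3 had 1.99 (adjusted p 0.0859) and AKR1B10 1.12 (adjusted p 0.0978). AKR1C1, AKR1C3 and AKR1B10 are also members of the NRF2 list, so the shifts of the family and of that list are not independent. Related members may share signal by cross-hybridisation, which was not tested. The metallothioneins (10 genes), small metal-binding proteins, had a median of 0.45 under the main setting and above 0 under every scaling (adjusted p 0.0125; adjusted p = 0.187 with an estimated correlation). By limma 0 of them passed singly, and MT1DP had the lowest adjusted p (1.06, adjusted p 0.141). Probes of related metallothioneins may share signal too, so the 10 may not be separate measurements, which was not tested. The HOX cluster genes (28 genes), which set positional identity, had a median of -0.31 and below 0 under every scaling (adjusted p 0.0125; adjusted p = 0.251 with an estimated correlation). The 5 called members were all of the HOXB cluster: HOXB8 fell 8.50-fold (adjusted p 0.0165), HOXB2 by a log2 value of -2.63, HOXB9 5.55-fold, HOXB5 2.80-fold and HOXB6 2.38-fold, while members outside HOXB went both ways, from -0.98 (HOXA2) to 0.91 (HOXA4).

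The calls as a whole were set against the array quality, the slides and the genome. After the spatial correction 98.0% of the 358 calls still passed in the same direction, which argues against uneven signal as the whole cause. Within slide 2 after the spatial correction the 354 called genes with a value there kept 91.5% of their median change, but they were chosen with those arrays. Genes were therefore also called after the spatial correction with 1 shControl array left out. Of the 2869 genes called without shControl 3, 2782 had a value on that array. These kept 50.3% of their median change of 1.04 against it (86.3% in the same direction). They were a longer set of smaller changes than those called without shControl 1 (721 genes) or shControl 2 (612 of 615 genes with a value on it). The latter sets had median changes of 1.32 and 1.37, with 98.0% and 96.8% kept against the array left out. A share from the slides and one from the group thus cannot be told apart, slide 1 holding shControl only. Of the 10 splits of the 6 arrays 1, the real one, gave 358 genes and the highest other 0, and 10 splits are too few to put chance under 5%. Called genes of 1 direction lay next to each other in 20 pairs, against at most 10 in 100 shuffled orders, and in 7 pairs outside the runs, matched by 2 of 100 shuffles, so copy number differences between the lines may lie behind some calls, as may shared regulation of neighbours, which was not tested.

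The lower signal of the chromosome 6 run, which takes in the long arm and begins on the short arm, had the strongest score of the runs. Within slide 2 it kept 99.6% of its size, although the run and its ends were chosen with those arrays too. On shControl 3, which shares slide 2 with the shMEK5 arrays, its median lay at 0.51, beside 0.40 and 0.46 on shControl 1 and 2. With that limit, these values argue against the slides as the whole cause. Of 100 shuffled gene orders 0 held a run as strong (score -12.7 against at most 3.68 in size), which argues against a random order. The drop grew with signal, with medians of -0.68, -0.80, -0.84 and -0.92 and 82.2%, 90.4%, 90.4% and 95.9% of genes lower in 4 groups from dimmest to brightest, and every array of each group lay on its side. A candidate explanation is that the shMEK5 line carries fewer copies of this stretch, or the shControl line more. No DNA was measured, so silencing along it stays open, as do clonal selection and an effect of MEK5 depletion, which the design does not separate because each hairpin stands for 1 line.

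The opposite shifts of the epithelial and mesenchymal lists had a difference of medians of 0.79, and 0.75 within slide 2 after the spatial correction, or 95.1% of its size. Random list pairs of like brightness reached at most 0.57, and 0% of 10000 draws were as large, but the draws ignore correlation between genes. Neither list passed camera with an estimated correlation (adjusted p 0.181 and 0.327), which was -0.008 for the epithelial and 0.066 for the mesenchymal list. The epithelial value lies below the preset 0.01, so a higher correlation is not what removed that call. Of 5 abundant stromal genes (DCN, LUM, COL1A1, COL1A2 and COL3A1) 0 were above background on all 3 shControl arrays, which argues against stromal cells in shControl. Among the gene families, the keratins (25 genes) and the claudins (12 genes) each had a median of -0.15. Camera called neither (adjusted p 0.0848 and 0.944), and by limma 1 keratin was lower and 1 claudin higher. A change of the cells toward an epithelial state with less MEK5 stays open as a hypothesis. MAP2K5 itself did not pass the test over all genes (adjusted p 0.155, and 0.0307 over the module alone). A difference between the lines that preceded the hairpin stays open too, and a further hairpin or line, which the labels do not name, would tell these apart.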
